A study of Mus musculus with 12 samples.

How the data were processed

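RNA immunoprecipitation followed by sequencing was carried out on mouse inner ear organoids, which are epithelial clusters grown in Matrigel from dissociated cochlear epithelium of newborn mice and then differentiated. Organoids received either a control lentivirus or a lentivirus that knocks down Rbm25, an RNA-binding splicing regulator. Each genotype had 2 numbered sets of libraries, each set read here as a culture. A set held an IP library (antibody against RBM25), an IgG library (control antibody) and a library labelled Input. This makes 12 libraries in 6 groups of 2. Libraries are named here by genotype, kind and culture number, and "depleted" stands for the Rbm25 knockdown, which the sample titles call KO. Same-numbered IP and IgG libraries were paired because their titles carry the same condition and number. The titles do not name cultures, so the pairing is an assumption. Nothing in the labels says that the cultures came from separate animals, so p-values measure only the spread between these samples, which may be technical.

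The submitters' processing notes name cutadapt 1.9.3, HISAT2 2.0.4 and the mouse build mm8. The peak caller, its version and the library used as its background are not given in the sources used here. Coordinates were checked against gene intervals of a GRCm38 gene table: 98.8% of the sites whose gene could be looked up (1977 of 2002) lay inside the gene they were assigned to, so the coordinates printed here, copied from the deposited lists, appear to be on GRCm38. They were not compared with mm8 gene intervals. Starts were counted from 0 in the lists, since width equalled end minus start in every row, and are printed counting from 1. No genome sequence was used, so exon, intron and motif content of the sites was not analysed here.

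Each library has its own deposited list of sites assigned to mRNAs, called per library. The fold enrichment of a site is the authors' ratio over the background of their peak caller. The score column is, per the file headers, −10 times log10 of the peak caller's p, and the deposited values start just above 50 and run to just over 3100. The false discovery rate is given by the authors in percent. Site width in bp was taken from the deposited lists as well. These values are the authors' own and describe or rank sites within their list. Peak numbers ran above the number of sites, which shows that the lists hold a part of the called peaks. Sequencing depth is unknown because no read counts were used here, so no test on counts was possible. A comparison of values at a common site across all 12 libraries was planned before the data were examined. It was not run because each list holds values only at its own sites.

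Sites of different lists were counted as overlapping when they shared 1 bp or more. For a comparison, the sites of 4 lists were merged into regions, and regions with a site in both lists of one group and in neither list of the other were counted. That count was set against the other ordered splits of the 4 lists into 2 and 2, 6 in all, so that the smallest one-sided p is 0.167. Numbers of sites and genes were compared by an exact permutation test of 2 libraries against 2, whose smallest two-sided p is 0.333. Neither of these tests can therefore pass 0.05, whatever the libraries hold. Shares of regions carry 95% Clopper-Pearson intervals, which cover the counting of regions only. Shares were compared by Fisher's exact test over regions, and these tests compare the lists of single libraries, not the conditions.

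Fixed before the data were examined were 18 gene lists: hair cell, supporting cell, stereocilia and deafness, cilium, Notch, Wnt, cell cycle, apoptosis, splicing factor, cytosolic ribosomal protein, oxidative phosphorylation, histone, long neuronal and synaptic, mesenchyme, glia, neuron, immune cell, and endothelial and melanocyte genes. Members were matched by symbol or gene identifier: of 1000 distinct gene names in the lists of sites, 983 carried an identifier and 979 of these were in the gene table. Each list was tested by a two-sided Fisher's exact test with Benjamini-Hochberg adjustment over the 18 lists, against the other genes with a site in the lists compared. Ontology and pathway terms written beside each gene in the deposited lists were tested the same way where 10 or more genes of the background carried them. Genes share sites and libraries, so these p-values describe the genes of these libraries.

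Named genes followed a rule set before the data were examined: Rbm25 in every library, then for each set of regions the 10 genes with the most regions, ties broken by the authors' fold in replicate 1, and from each gene list the 2 members with the highest mean fold. Predicted gene names were counted and not named. Genes named outside this rule, including further members of a list or term, were chosen after their values were seen.

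Alternatives were an overlap of 50% of a site, genes in place of regions, sites at or above the median fold of their list, sites of 100 bp or more, lists thinned at random to the shortest (median of 100 draws), same-numbered libraries only, other gene backgrounds, and leaving out each library. A rule that ignores sites with under an eighth of the fold, a ratio of 8, was added after seeing the data. The region counting was tested on simulated data and recovered 200 of 200 planted regions among 450 in a simulation of the control IP-specific comparison. Simulated sites lay far apart, were shifted by less than their width and were never missing from a replicate. Full recovery was therefore certain and checks only the counting itself. On simulated gene lists for that comparison, a 10-member list with an odds ratio of 10 was called in 67% of 1000 simulations with Bonferroni correction. The 5-member lists were never called, as so few members cannot reach the corrected threshold. No real list had 10 members with a control site, and the most was 9, so the 67% applies to none of them. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.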

Results

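RBM25-bound RNA was profiled in mouse inner ear organoids with and without Rbm25 knockdown. The data are 12 lists of sites on mRNAs, from what are read here as 4 cultures. Rbm25 itself, the targeted gene, had sites in 1 of the 4 IP libraries and in no IgG library. Both sites lay on chromosome 12 in depleted IP 1, at 83664140 to 83664259 with a fold of 1237 and at 83668092 to 83668173 with a fold of 1873, each at a false discovery rate of 1.82%. Control IP 1, control IP 2 and depleted IP 2 listed no site in Rbm25. The lists give no level of unprecipitated Rbm25 RNA, so the extent of the knockdown was not analysed here.

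The control IP libraries listed 594 and 593 sites in 430 and 432 genes, and the control IgG libraries 442 and 430 sites in 327 and 318 genes. The IP lists held 593.5 ± 0.707 sites and the IgG lists 436.0 ± 8.49 (SD, n = 2 each), with an exact permutation p of 0.33, the smallest this test allows. After depletion the IP libraries listed 813 and 165 sites in 540 and 110 genes, and the IgG libraries 498 and 511 sites in 374 and 378 genes. The depleted IP lists held 489.0 ± 458.2 sites (SD, n = 2), with 1 list longer and 1 shorter than both control IP lists. Median site width was between 115 and 162 bp in these 8 lists. The authors' median fold was 241 and 323 in control IP, 35.2 and 33.7 in control IgG, 347 and 1386 in depleted IP, and 55.6 and 44.6 in depleted IgG. Sites with a false discovery rate under 5% occurred in depleted IP 1 alone, where they made up 69.5% of the list (565 sites). The lowest rate was 16.2% and 17.4% in the control IP lists and 25.5% in depleted IP 2. A rate of 100% was given to 14.3% and 13.0% of control IP sites and to 84.2% and 86.7% of control IgG sites. After depletion it was given to 11.9% and 22.4% of IP sites and to 45.6% and 43.8% of IgG sites. Such sites were kept, as no comparison used this rate.

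**Figure D1:**
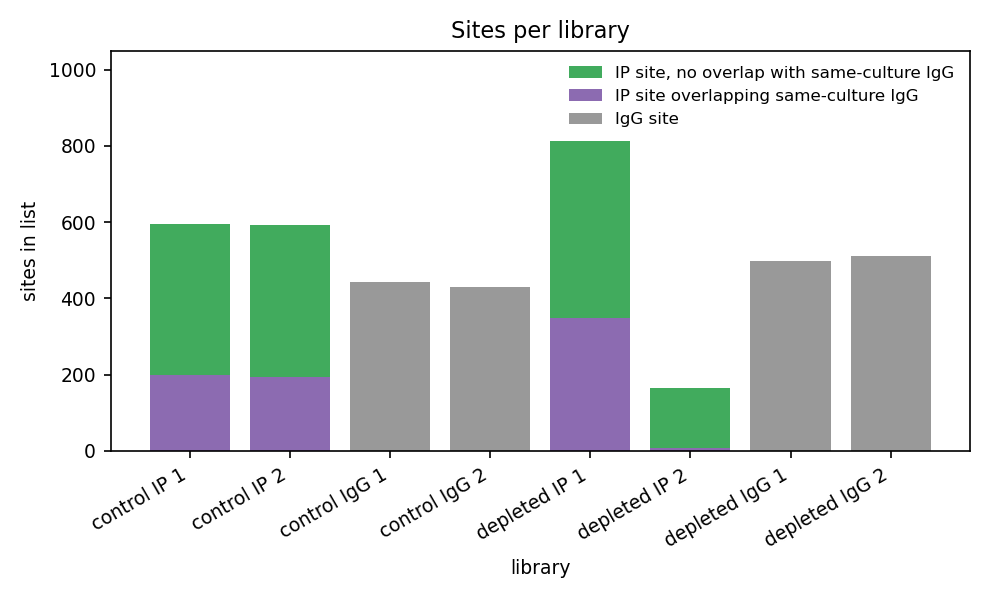
Number of sites listed per library (bars from 0), with IP sites divided by whether they overlap a site of the IgG library of the same culture by 1 bp or more. Control IP lists hold 594 and 593 sites, while depleted IP lists hold 813 and 165.

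The lists labelled Input held no independent sites. Each was, row for row, the IP list of its culture without the sites that overlapped the IgG list of that culture: 396 of 594 sites in control culture 1, 399 of 593 in control culture 2, 464 of 813 in depleted culture 1 and 158 of 165 in depleted culture 2, with 0 exceptions. They are treated here as the authors' IgG-filtered IP lists and give no measure of RNA abundance.

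The replicate control IP lists named nearly the same transcripts. Of the 594 sites of control IP 1, 570 (96.0%, 95% interval 94.0 to 97.4%) overlapped a site of control IP 2, and 451 sites had identical boundaries in both. Across the 570 shared regions, which are not independent replicates, the authors' folds of the replicates had a Spearman correlation of 0.93. Hoxc4, a homeobox transcription factor, carried the highest fold of both lists (85670 and 77526 on chromosome 15), a gene chosen after its value was seen. The control IP 1 site overlapped a control IgG 1 site, so the highest fold of the IgG-filtered list of culture 1 was 15084. In culture 2 the Hoxc4 site stayed in the filtered list. Control IgG sites overlapped between replicates at 81.2% and depleted IgG sites at 95.4%. Depleted IP 1 and depleted IP 2 had 6 overlapping sites, 0.738% of the first list and 3.64% of the second. Depleted IP 1 overlapped most with depleted IgG (42.9% and 43.9% of its sites), and depleted IP 2 with control IP (41.8% and 37.6%), against 4.85% and 4.24% with depleted IgG.

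**Figure D2:**
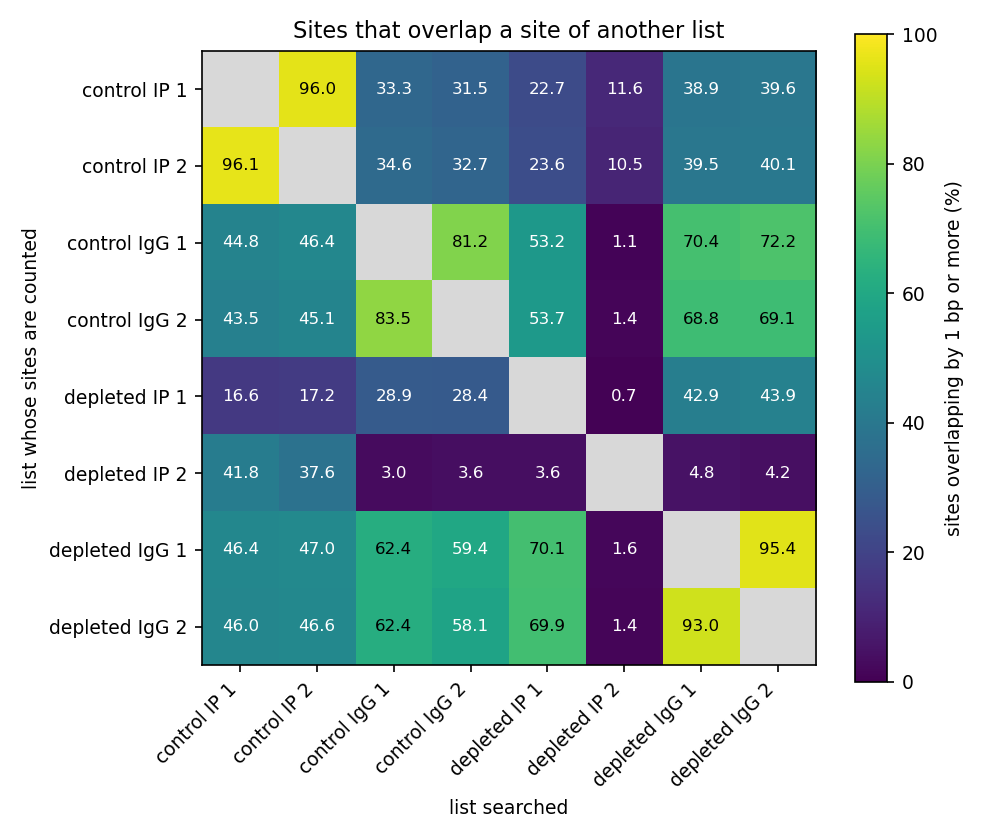
Percent of the sites of each list (rows) that overlap a site of another list (columns) by 1 bp or more, for the 8 IP and IgG libraries; grey cells compare a list with itself. Control IP replicates overlap at 96.0%, depleted IgG replicates at 95.4%, and depleted IP 1 overlaps depleted IP 2 at 0.738%.

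The first comparison of the design asked which transcripts the RBM25 antibody recovered in control organoids beyond the IgG control. Regions present in both control IP lists and in neither IgG list numbered 364, in 274 genes, out of 570 regions shared by the IP lists. Evc, a component of the ciliary Ellis-van Creveld complex, had 3 such regions with folds up to 8052 and 7267 in the replicates, the strongest at 37310178 to 37310367 on chromosome 5. Col9a1, a chain of cartilage and tectorial membrane collagen IX, had 4 regions with folds up to 40.3 and 74.8. Ccnl2, a cyclin L tied to pre-mRNA splicing, and Akap8l, a nuclear anchoring protein, had 3 regions each, with folds up to 1126 and 1316 in Ccnl2 and up to 292 and 567 in Akap8l.

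Further genes with several regions were Ogdhl, an oxoglutarate dehydrogenase-like enzyme (fold 6563 and 6441), Wdr8 (5418 and 6501), the spindle checkpoint gene Mad1l1 (5071 and 3273), the Integrator subunit gene Ints9 (4628 and 3468), D5Ertd579e (3424 and 3335) and the bromodomain gene Brd9 (3407 and 3511), each with 2 regions. Among cilium genes, Ift172, an intraflagellar transport subunit, had a region on chromosome 5 at 31266233 to 31266423 (4778 and 3976), and Celsr1, a planar polarity cadherin, one on chromosome 15 (349 and 334). Ptk7 was the third cilium gene with a control site and did not enter the set. All 3 cell cycle genes with a control site were in the set: Mcm4 (341 and 647) and Mcm7 (382 and 274), subunits of the replicative helicase, and Ccnb2, cyclin B2. With 3 members the smallest p that Fisher's exact test can give for this list is 0.0748, the value it had (adjusted p = 1), so the test could not decide.

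Of 9 splicing factor genes with a control site, 3 were in the set, namely Ddx17 (112 and 192), an RNA helicase, Hnrnpu (124 and 104) and Srsf5, against 42.2% of all genes. Acin1, Luc7l2, Prpf40b, Snrnp70, Srsf2 and Srsf7 lay outside it (Fisher's exact test, odds ratio 0.68, adjusted p = 1). Of 9 cytosolic ribosomal protein genes 5 were in the set, with Rpl37a at 94.6 and 238, and of 6 histone genes 3, with Hist1h1b at 176 and 285 and Hist1h1d at 43.3 and 64.2. Ribosomal protein and histone genes have near-identical copies, so the assignment of their sites is uncertain. The Wnt target Axin2 was in the set (217 and 134), and the Wnt receptor gene Fzd1 was not. Membership rests on regions, and some members also had IgG sites elsewhere in the gene. These included Axin2, the ribosomal protein gene Fau and, in control IgG 1, Rpl37a. Genes in both control IP lists and in no control IgG list numbered 253, against 274 genes in the set. Of 7 mesenchyme genes the set held Sparc, at the low folds of 2.34 and 5.19. The hair cell, supporting cell, stereocilia, apoptosis, immune and oxidative phosphorylation lists had 1 member each with a control site, outside the set, and 5 of the 18 lists (Notch, neuron, long neuronal, glia, endothelial and melanocyte) had none. None of the 18 lists passed Fisher's exact test after adjustment, and none had an unadjusted p under 0.05, which 4 of them had enough members to reach. Of 173 ontology and pathway terms, 0 passed after adjustment and 7 had an unadjusted p under 0.05, with 24 of 37 protein complex genes (p = 0.00556, adjusted p = 0.833) at the top by Fisher's exact test.

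The opposite set, 173 regions in 129 genes, was found in both control IgG lists and in neither IP list. Col1a1 and Col3a1, fibrillar collagens, had 6 regions each, with folds up to 277 and 269 in Col1a1 and up to 132 and 159 in Col3a1. Col1a1 also had sites elsewhere in the gene in both control IP lists. Ahnak had 4 regions (58.6 and 56.2) and Trappc10, a vesicle tethering gene, 3 (22843 and 15775). The ubiquitin ligase gene Itch (23343 and 7117), Nrip1, Polb, Lrrfip1, Ptpn13 and Col27a1 had 2 regions each. Barhl1, a hair cell homeobox gene (158 and 269), Otog, which encodes the tectorial membrane protein otogelin (351 and 212), and Myh14, a deafness gene encoding a non-muscle myosin (21.98 and 14.1), each had an IgG region and no site in control IP. Barhl1 also had the site with the highest fold of depleted IP 1 (23738), and sites in both depleted IgG lists. Of 22 genes annotated to proteinaceous extracellular matrix, 11 were in this set (Fisher's exact test, odds ratio 4.31, p = 0.00123, adjusted p = 0.177). Here 0 of 173 terms passed after adjustment, and 14 had an unadjusted p under 0.05.

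The 364 regions were the highest of the 6 ordered splits of the 4 control lists, with 173 in the reverse split and 0 in each of the 4 mixed splits, a one-sided exact p of 0.17 that is the smallest possible. On average 33.0% ± 0.873 of control IP sites overlapped an IgG site (SD over 2 IP libraries). The count was 157 with sites at or above the median fold of their list, 199 with sites of 100 bp or more, and 192 with lists thinned to the shortest.

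In depleted organoids the same comparison gave 3 regions: Gas2 on chromosome 7 (124.5 and 1039), a growth arrest gene, Wdr89 on chromosome 12 (104.2 and 77.9), and Rps3 on chromosome 7 at 99480007 to 99480213 (40.9 and 85.96), which encodes a small ribosomal subunit protein. The Gas2 and Wdr89 regions were also listed in control IP 2. The reverse set of 139 regions in 112 genes was larger. It held Mical3 (18806 and 29045), Galnt7 (4157 and 11182), Ibtk (2521 and 3880), Ccdc30, Gmeb1, Klhl20, Kiz, Ptpn13 and Cyfip2 with 2 regions each. Its list members included Ptk7, the apoptosis gene Bax, the U1 protein gene Snrnp70, Rps12 and Rpl37a. The count of 3 was not the highest of the splits (one-sided exact p = 0.667), and mixed pairs of an IP and an IgG list gave 0 to 25 regions.

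The depleted count depended on which IP library was used. Without depleted IP 1 the count was 157 and without depleted IP 2 it was 439, against 3 with both. Depleted IP sites overlapped an IgG site in 43.4% of cases in replicate 1 and 4.55% in replicate 2, a mean of 23.98% ± 27.5 (SD, n = 2), so the difference from control organoids was smaller than the spread between depleted replicates. The count was 8 with genes in place of regions, 0 with sites at or above the median fold and 1 with thinned lists.

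The next comparison asked which control IP regions were no longer listed after knockdown. Of 570 regions in both control IP lists, 384 (67.4%) in 287 genes were in neither depleted IP list, and 2 regions, in Rps3 and the splicing factor gene Rbm39 (277 and 131), were in both depleted lists and in neither control list, the Rbm39 region being listed in both depleted IgG lists as well. Dsp, which encodes the desmosomal protein desmoplakin, lost 3 regions (control folds up to 1268 and 1057, the strongest at 38185096 to 38185262 on chromosome 13). Klhl20, a ubiquitin ligase adaptor gene (522 and 1049), and Akap8l also lost 3. Ogdhl, Mad1l1, Ints9, Brd9, the phosphatase gene Ptpn21 (3267 and 2803), the epithelial transcription factor gene Elf3 (2834 and 2503) and Zfp410 (2670 and 2742) lost 2 regions each, and none of these genes had a site in any depleted IP or IgG list apart from Klhl20, which had depleted IgG sites.

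By group, the lost set held 2 of 5 cilium genes (Celsr1 and Ptk7), 1 of 3 Wnt genes (Axin2), 1 of 4 cell cycle genes (Mcm4), 1 of 2 apoptosis genes (Bax), 4 of 19 splicing factor genes (Ddx17, Hnrnpu, Snrnp70 and Srsf5), 6 of 24 ribosomal protein genes including Rpl37a and Rpl18, 3 of 7 histone genes (Hist1h1b, Hist1h1d and Hist1h4d) and 1 of 4 mesenchyme genes (Sparc). The totals count genes with a site in any of the 4 IP lists. Genes listed only after depletion could not be lost, so these shares and the tests of this set do not measure loss among control genes. Control IP 1 listed 6 splicing factor and 8 ribosomal protein genes. The loss refers to regions in the IP lists: Ddx17, Celsr1, Axin2, Sparc and Rpl23a had sites elsewhere in the gene in depleted IP 1, with folds up to 279, 89.6, 31.8, 25.3 and 302. Of the 384 lost regions, 104 were listed in both depleted IgG lists, a count made after the values were seen, and these included the lost regions of Ptk7, Bax, Snrnp70, Rpl37a and Rpl18. None of the 18 lists passed Fisher's exact test, and none had an unadjusted p under 0.05 (smallest 0.456, adjusted p = 1). Counting genes listed only after depletion, 7 lists had enough members to reach an unadjusted p under 0.05. Of 229 terms, 0 passed after adjustment and 8 had an unadjusted p under 0.05. Kinetochore genes led with 8 of 10 in the lost set, among them Kif2c, Mad1l1, Nup160 and Tpr (Fisher's exact test, odds ratio 8.65, p = 0.00251, adjusted p = 0.574).

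The 384 lost regions were the highest of the 6 splits, the others giving 2 to 14 (one-sided exact p = 0.17, the smallest possible). The count fell to 37 when lists were thinned to the 165 sites of depleted IP 2. Random thinning also leaves fewer regions shared by both control lists, so thinned counts cannot be read as a smaller share lost. The count was 248 for genes in place of regions and 209 for sites of 100 bp or more. Among the authors' IgG-filtered lists, labelled Input, 301 regions in 232 genes were lost and 2, in Wdr89 and Rps3, were gained. The IgG filter made some of these calls. The Wdr89 region was listed in control IP 2 and in both control IgG lists. Some regions counted as lost were still listed in depleted IP, such as those of Rsph3b (fold 503.58 in depleted IP 1) and S100a13 (665.03 in depleted IP 2). Akap8l, Ogdhl, Mad1l1, Ints9, Brd9, Ptpn21, Elf3, Zfp410, Nckap5 and Kif2c had the most lost regions there. This count was the highest of its splits (1 to 14 in mixed splits, one-sided exact p = 0.17), and it was 177 with sites at or above the median fold, 159 with sites of 100 bp or more and 48 with thinned lists.

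Control IP-specific regions were then looked up in each depleted list. Of the 364 regions, 15 (4.12%, 95% interval 2.32 to 6.71%) were found in depleted IP 1, 53 (14.6%, 11.1 to 18.6%) in depleted IP 2, 0 in both and 296 (81.3%) in neither, a mean of 9.34% ± 7.38 (SD, n = 2). In the depleted IgG lists 34 (9.34%) and 35 (9.62%) were found. Of the 177 regions present in all 4 control lists, 114 (64.4%) were found in depleted IP 1 and 2 (1.13%) in depleted IP 2, while the depleted IgG lists held 171 and 172 of them. Depleted IP 1 thus listed IP-specific regions less often than IgG-shared ones (Fisher's exact test over regions, odds ratio 0.0238, adjusted p = 3.09e-53), and depleted IP 2 more often (odds ratio 14.9, adjusted p = 7.15e-08).

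**Figure D3:**
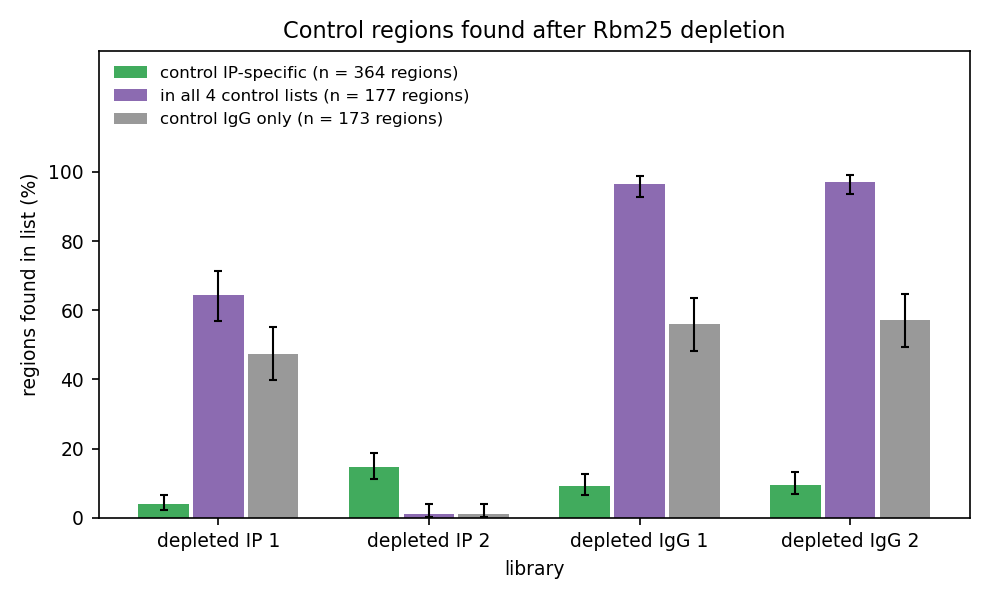
Percent of control regions (y axis) found in each depleted library (x axis) for regions in both control IP lists only, in all 4 control lists, and in both control IgG lists only; error bars are 95% Clopper-Pearson intervals. Control IP-specific regions are found at 4.12% in depleted IP 1 and 14.6% in depleted IP 2.

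Genes behind these regions, chosen after their values were seen, differed between the depleted libraries. Depleted IP 1 listed regions in Ybx1, an RNA-binding protein gene (fold 22.95 in control IP 1 and 85.2 in depleted IP 1), Id2 (109 and 11.4), Gtf2i (241 and 14.8), Col9a2 (33.9 and 13.0) and Rsph3a and Rsph3b, radial spoke genes with similar sequences. Depleted IP 2 listed regions in Rnf165 (15084 in control IP 1 and 177.9 in depleted IP 2), Ern1 (9562 and 19.2), Ift172 (4778 and 11.3) and Kdm2b (6159 and 8.33), and also in Skp2 (36.7 and 66494), Ccnb2 (36.1 and 41548) and Smarca4 (7.86 and 8106). The depleted IP 2 site of Ift172 had a false discovery rate of 100%. Of the 15 regions in depleted IP 1, 11 had folds within a factor of 8 of control IP 1, 3 were higher in control IP 1 and 1 in depleted IP 1. Of the 53 in depleted IP 2, 30 had a fold at least 8 times higher in control IP 1, 23 had one at least 8 times higher in depleted IP 2, and 0 lay between. The background behind each list's folds is not known, so these ratios describe the lists and were not read as a measure of binding.

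**Figure D4:**
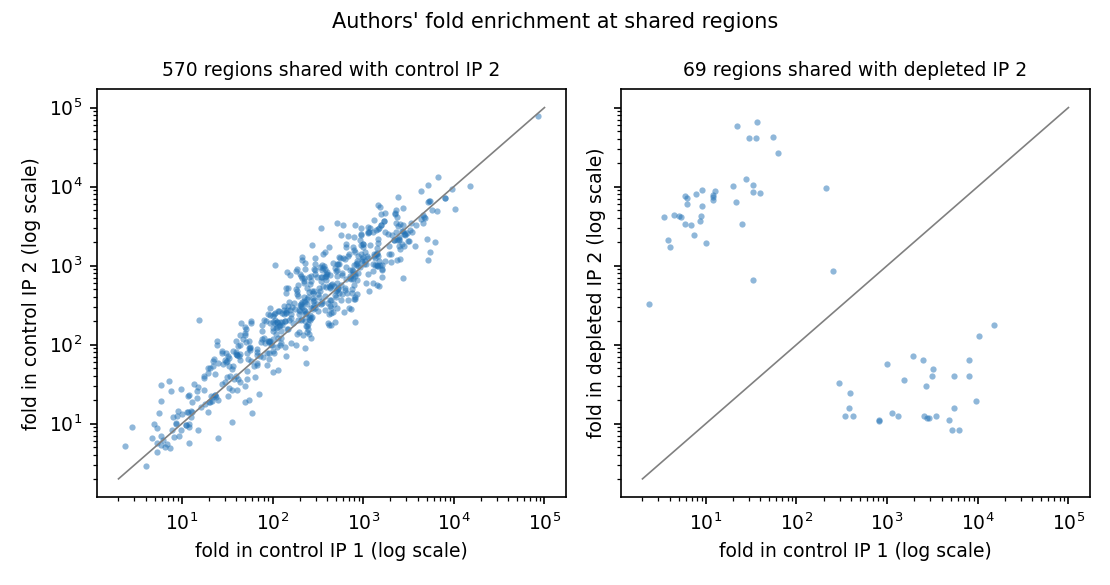
Authors' fold enrichment per shared region on log axes, with control IP 1 on the x axis and control IP 2 (left, 570 regions) or depleted IP 2 (right, 69 regions) on the y axis; each point is a region and the line marks equal folds. Of the 570 regions, 567 have folds within a factor of 8 of each other, whereas of the 69 regions 30 are at least 8 times higher in control IP 1 and 38 at least 8 times higher in depleted IP 2.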

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

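The rule on an eighth of the fold was chosen after the results were seen, and all other alternatives before. Of 72 alternatives, 54 left a result within the bounds set for it (1.5 times a count, 1 SD of a mean). Where a mean rests on 2 IP libraries, leaving out 1 of them always moves it by less than 1 SD. Those alternatives could therefore not leave the bounds. For the depleted share of IP sites overlapping IgG, the SD (27.5) exceeded the mean (23.98%), so no fall could leave the bounds either. That share was 10.7% with sites at or above the median fold and 7.88% with thinned lists. All 8 of its alternatives count among the 54. The 54 also include the 11 gene-list alternatives. In the main gene-list tests most lists had too few members to reach an unadjusted p under 0.05 by Fisher's exact test. With sites at or above the median fold of their list, control IP-specific regions numbered 157, depleted IP-specific regions 0, IgG-filtered regions lost 177, and the control share of IP sites overlapping IgG was 31.7%. With sites of 100 bp or more the counts were 199 control IP-specific, 209 control IP regions lost and 159 IgG-filtered regions lost. With lists thinned to the shortest they were 192 control IP-specific, 1 depleted IP-specific, 37 lost and 48 IgG-filtered lost; these 3 settings use fewer sites by construction. With genes in place of regions, 253 were control IP-specific, 8 depleted IP-specific and 248 lost, and the cause was not tested. Ignoring sites under an eighth of the fold, chosen after seeing the data, gave 5 depleted IP-specific and 533 control IP-specific regions. Leaving out each library gave 373 to 387 control IP-specific, 3 to 439 depleted IP-specific (157 without depleted IP 1, 439 without depleted IP 2), 392 to 515 lost and 312 to 353 IgG-filtered lost regions, a control IgG overlap of 32.1 to 33.95%, a depleted one of 4.55 to 43.4%, and 4.12 to 14.6% of regions found after depletion. With the replicate block, which pairs same-numbered libraries, the control and depleted shares were 33.0% and 23.6% and the share found 9.67%, all 3 within the bounds; counts of regions had no such alternative. None of 11 alternatives made a gene list pass. The background of genes in both control Input lists was not run because those lists are filtered IP lists, and alternatives for site values, motif and genome annotation were not run. Depth is unknown, so absence from a list is no measure of absence of binding.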

Other observations

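Of the tests below, the share of the strongest sites, both exchanges of libraries, the boundary comparison, the comparison of neighbouring sites and the gene groups of the depleted libraries were chosen after the results were seen. Depleted IP 1 had 315 genes with a site that overlapped none of its IgG sites, and 49 of them also had a site in that IgG list. They included the splicing factor genes Srrm1 (fold up to 171), Srrm2 (95.3), Sf3b2 (329), Prpf39 (109), Pnn (53.0), Clk1 (355) and Rbm25 itself. In all, 10 of 19 splicing factor genes were among the 315, against a background of 1000 genes with a site in any IP or IgG list (Fisher's exact test, odds ratio 2.46, p = 0.0769, adjusted p = 0.692). Of these, Prpf40b and Srsf2 had sites in depleted IgG 1 as well, and Prpf39 in depleted IgG 2. Of 25 ribosomal protein genes 14 were among them, Rpl4 and Rplp2 with IgG sites as well, with Rps9 at a fold of 367, Rpl23a at 302 and Rps3 at up to 569 (Fisher's exact test, odds ratio 2.85, p = 0.0143, adjusted p = 0.258). The supporting cell genes Sox9 (22.5) and Epyc (up to 12.04), the Wnt feedback gene Rnf43 (75.5), the cell cycle inhibitor gene Cdkn1c (90.2) and Myh14 (3768), which had an IgG site as well, were also listed. Of the 18 lists, 0 passed after adjustment and 1, the ribosomal proteins, had an unadjusted p under 0.05.

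Depleted IP 2 had 106 genes with a site that overlapped none of its IgG sites, and 7 of them also had a site in that IgG list. The 106 included cyclin B2 (Ccnb2, fold up to 41548), Mcm7 (15.6, at a false discovery rate of 100%), the splicing factor gene Srsf1 (568), Rpsa (up to 770) and Rplp1 (up to 420). Cell cycle genes made up 2 of 4 (Fisher's exact test, p = 0.0579, adjusted p = 1), and 0 of the 18 lists passed. Regions listed in a single library were most numerous in depleted IP 1, with 399 of 1548 merged regions, and 264 regions were listed by the control IP libraries alone. Neighbouring sites of a gene had folds within 5% of each other in 120 of 1134 pairs (10.6%), against 1.79% of random pairs of different genes within a list.

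The depleted IP replicates shared few sites, while control IP replicates shared nearly all. The shorter list of depleted IP 2 was set against the strongest 165 sites of control IP 2, of which 100% (95% interval 97.8 to 100%) were found in control IP 1, compared with 3.64% for depleted IP 2 in depleted IP 1. Since 570 of 593 control IP 2 sites were found in control IP 1, most of any 165 of them had to be found as well. The comparison therefore restates the control overlap and is no separate test of list length. An exchange of IP and IgG libraries in a depleted culture would place the list labelled IgG apart from the other IgG list, yet 95.4% of depleted IgG 1 was found in depleted IgG 2 against 43.9% of depleted IP 1. An exchange with a control IP library would leave a control list out of place, yet control IP 1 overlapped control IP 2 at 96.0%, against 22.7% and 11.6% for the depleted lists. Shallower sequencing, a lower yield of antibody target after knockdown, a difference in knockdown between the cultures, and a single wrong label stay open and were not tested.

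Regions shared by control IP 1 and depleted IP 2 were mostly strong in one library and weak in the other, with 1 of 69 within a factor of 8. Spearman's correlation of the folds was -0.62 over the 69 regions, some of which lie in the same gene. Reads carried over between libraries may give such a split, with the weak fold following the strong one. Among the regions strongest in depleted IP 2 the correlation was 0.73 (24 regions, one-sided permutation p = 3e-05), but among those strongest in control IP 1 it was 0.26 (25 regions, p = 0.101). Both permutations treated regions as independent, although some lie in the same gene, so these p-values may be too small. Carry-over stays open as a hypothesis. Separate amplification of few molecules in each library and a change in RBM25 binding with knockdown also stay open and were not tested.

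Of the overlapping control IP sites, 79.1% had identical boundaries in both replicates. The share was no lower between IgG replicates, at 83.6% in control and 98.7% in depleted organoids. Shared boundaries were thus not particular to control IP, and the explanations below were weighed for control IP only. Exon ends could fix boundaries in any library: the control IP 1 sites also found in control IP 2 and depleted IgG 2 had identical boundaries in 62.0% (95% interval 55.4 to 68.2%) of cases in depleted IgG 2 and 75.6% in control IP 2, and of the 6 lists compared the intervals overlapped for depleted IP 1 and depleted IP 2. A single precipitate or library divided before sequencing could make the lists alike. Of 465 control IP 1 sites with a p score of 3100 or more, 3 (0.645%, 95% interval 0.133 to 1.87%) were absent from control IP 2, which neither excludes nor requires such a division. Biological similarity of the cultures was not tested.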
